A study of Homo sapiens with 12 samples.

How the data were processed

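Messenger RNA was sequenced from 12 libraries in 3 groups of 4. Per the labels, every library came from CS1AN, a fibroblast line derived from a person with Cockayne syndrome that carries mutations in CSB, the DNA repair and transcription protein encoded by ERCC6. One group stably expressed full-length wild-type CSB (CSB WT), one expressed CSB altered in its ubiquitin-binding domain (UBD mutant), and one carried a vector for green fluorescent protein without CSB (GFP control). Per the labels' protocols, RNA was extracted with a column kit and messenger RNA was captured on poly-T beads and fragmented. The protocol text offers both a standard and a strand-specific library without saying which was made, so reads of antisense and overlapping genes could not be told apart. The labels number the replicates but do not say whether they were separate cultures, so the p-values measure the spread between these samples, which may be technical.

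The authors deposited whole-number counts per gene, not normalized per the file headers, with 1 table per library and 48162 genes in each. Per the submitters' processing notes, CASAVA, without a version, and the hg19 build were used. The aligner, the counting tool, the annotation release and the strand setting are not given in the sources used here. Total counts ran from 19880498 to 27112460 per library, and between 20257 and 22144 genes had a count. Of the gene identifiers, 33930 had a symbol and 45342 were found in the GENCODE 29 annotation, which left 2820 without a match. That annotation is on another build than the authors' counts, so it was used only for names, gene class, chromosome and the order of neighbouring genes, and no coordinates are given. No line of the files was without a gene.

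Counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 after normalization by trimmed means (TMM, factors 0.982 to 1.017). All 12 libraries entered 1 model with the group as its only term, so that the groups shared an estimate of the spread. The default low-count filter of edgeR (at least 10 counts in enough libraries, scaled to the library size, and 15 in total) left 15029 genes. P-values were adjusted over these genes by the Benjamini-Hochberg method, and a gene was called changed at an adjusted p under 0.05. Levels are given as CPM, counts scaled to the TMM library sizes, as mean ± SD over n = 4 libraries, and log2 fold changes carry standard errors (SE) derived from the test. The biological coefficient of variation was 7.6%. No 2 libraries of a group agreed within sampling noise, since the chi-square over its degrees of freedom lay between 5.61 and 15 for pairs within groups. Where a group held 1 to 3 counts of a gene, the ratio of counts is given with a 95% interval that covers counting error only, and sequencing reads are not independent molecules.

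Before the data were examined, 30 gene lists, the comparisons, the tests and the rule for naming genes were fixed. Lists with at least 8 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01 between genes and adjusted over 27 lists. The same lists were tested again with the correlation estimated from the data and with fry, which asks whether a list's genes move on balance in 1 direction. The genes named for each comparison were 12 fixed genes, the 8 largest rises and the 8 largest falls, and the 3 members with the smallest adjusted p in the direction of each called list. The largest changes were taken among protein-coding genes with a mean of at least 5 CPM, an adjusted p under 0.05 and no overlap between the libraries of both groups. Fewer than these are named in places, and genes chosen after their values were seen are marked as such.

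The steps were checked on simulated counts made from the real means, dispersions and library sizes for CSB WT against GFP control over 15029 genes. There, 56.7% of 67 genes changed by 0.5 on the log2 scale were recovered, as were 89.6% of 67 changed by 1 and 98.5% of 66 changed by 2. Members of the RNA polymerase III list were also raised by 0.5, and that list was called. Of the 202 calls, which include such members, 14 were false. Alternatives tried were size factors by relative log expression (RLE), DESeq2 1.42.0, no filter, a model of only the groups compared, a replicate block, a fold threshold, and leaving out each library in turn. Added after seeing the data were a correction for GC content and transcript length, thinning to the smallest library, and list tests without the genes of 5 autosomes. Sex chromosomes were left out of the chromosome summaries, and 3 genes were kept out of all tables of single genes because they could describe the donor.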

Results

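The series measured messenger RNA in 3 stable lines made from CS1AN, a fibroblast line from a person with Cockayne syndrome, a disorder of transcription-coupled DNA repair. CSB, the product of ERCC6, is a chromatin-remodelling ATPase. The lines expressed wild-type CSB (CSB WT), CSB with an altered ubiquitin-binding domain (UBD mutant) or only a vector for green fluorescent protein (GFP control), with 4 libraries each. Total counts of replicates 1 to 4 were 20766319, 25327414, 23534512 and 25147352 in CSB WT, 21014407, 24391031, 19880498 and 24092770 in GFP control, and 27112460, 25003116, 22109997 and 25453556 in UBD mutant. The design text names the mutant against wild-type CSB as its question, and the title places the study at transcription of ribosomal RNA and at nucleolin. Ribosomal RNA itself has no poly(A) tail and was not captured by this assay.

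ERCC6 (ENSG00000225830, chromosome 10), the gene carried by both CSB transgenes, was measured first because it checks the labels. It stood at 4.36 ± 0.606 CPM in GFP control, 36.6 ± 8.85 CPM in CSB WT and 212 ± 32.9 CPM in UBD mutant (SD, n = 4). ERCC6 was higher in CSB WT than in GFP control by 3.07 on the log2 scale (SE 0.18, adjusted p = 3.51e-10), and higher in UBD mutant than in CSB WT by 2.53 (SE 0.14, adjusted p = 1.37e-10). Counts over ERCC6 come from the endogenous gene and the transgene together. ERCC6 in UBD mutant thus stood at 5.77 times its level in CSB WT, so protein variant and transgene level differ together in every comparison with UBD mutant.

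**Figure D1:**
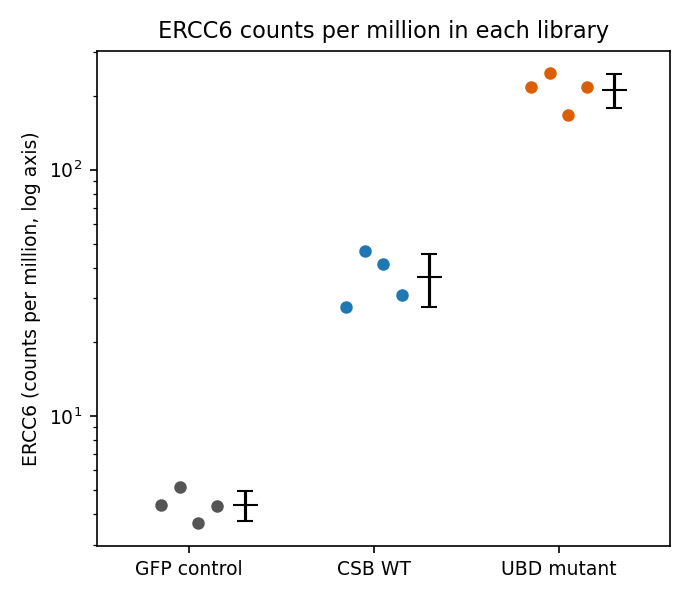
ERCC6 in each of the 12 libraries, in CPM on a log axis; points are libraries, and the bar beside each group is its mean with SD (n = 4). GFP control libraries lay between 3.66 and 5.14 CPM, CSB WT between 27.6 and 46.5 CPM, and UBD mutant between 167 and 246 CPM.

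The libraries separated by line over all tested genes. The first component held 43% of the variance and the second 35.3%, and on them each group of 4 libraries formed a tight set apart from the others. The third component held 4.3%. Each group is a stable line of its own, and whether it grew from 1 clone or a pool is not stated, so the transgene cannot be separated from other differences between the lines.

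**Figure D2:**
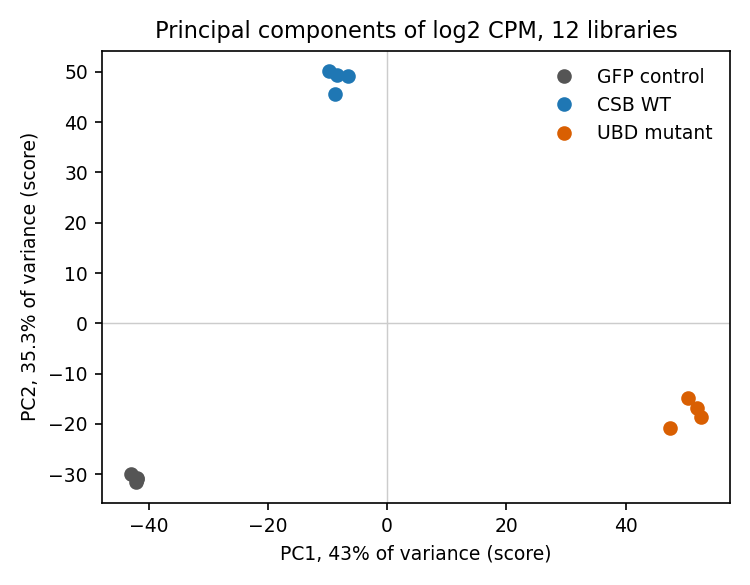
Scores of the 12 libraries on the first 2 principal components of log2 CPM (43% and 35.3% of the variance); each point is a library, coloured by line. The 3 lines form separate sets, with GFP control between -43 and -41.9 on PC1, CSB WT between -9.7 and -6.5, and UBD mutant between 47.4 and 52.7.

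Wild-type CSB against the GFP control asked what differed when the CSB-mutant fibroblasts carried functional CSB. Genes of glycolysis and the hypoxia response, of the extracellular matrix, of replication-dependent histones and of cholesterol synthesis were higher in CSB WT, and factors of ribosome assembly were lower. These lists were called by camera at the preset correlation, and none was called with an estimated correlation (adjusted p = 0.193, 0.238, 0.301, 0.931 and 0.931 in that order). In all, 6666 of 15029 tested genes changed (44.4%), 3267 higher and 3399 lower in CSB WT, and 1298 of these moved at least 2-fold, 892 higher and 406 lower. Genes nearly silent in one line and well expressed in the other led both directions. COL6A6, a collagen VI chain, rose from 0.0470 ± 0.0406 to 14.7 ± 0.509 CPM (log2 fold change 8.20, SE 0.23, adjusted p = 2.84e-14). BRINP3 fell from 38.3 ± 6.90 CPM in GFP control to 2 counts in all of CSB WT, a ratio of 1800 with a 95% counting interval of 498 to 14900.

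Other large rises in CSB WT included FBLIM1, a filamin-binding adhesion protein (6.78, SE 0.18), CA9, a carbonic anhydrase induced by hypoxia (6.23, SE 0.34), and the glycosyltransferase GALNT16 (5.82, SE 0.12). BMP4, a secreted morphogen, rose by 4.83 (SE 0.18) on the log2 scale. UGT2B7 rose by 4.71 (SE 0.15), with its reads uncertain because its family holds near-identical copies. Large falls were those of VAMP5 (-8.54, SE 0.35), a vesicle fusion protein, the protease TLL1 (-6.96, SE 0.15), FSTL5 (-6.44, SE 0.11) and the phosphodiesterase PDE3A (-5.50, SE 0.12). The muscle-associated genes ANKRD2 and DMD, which encodes dystrophin, fell as well (-5.44, SE 0.12, and -5.37, SE 0.22). MT1E, a metallothionein with near-identical family members, fell by 7.23 (SE 0.34). All of these had an adjusted p of 1.61e-10 or below in edgeR's test.

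Glycolysis and hypoxia targets rose as a list in CSB WT (camera adjusted p = 4.59e-12, median log2 fold change 0.45). Of the 37 tested members, 27 rose, 3 fell and 7 did not pass the test, and 30 rose and 3 fell adjusted over the list alone. GPI, the second enzyme of glycolysis, went from 128 ± 2.90 to 320 ± 3.52 CPM (1.32, SE 0.04, adjusted p = 5.87e-14), and ERO1A, an oxidase of the endoplasmic reticulum encoded on autosome 14, from 134 ± 1.24 to 299 ± 16.9 CPM (1.16, SE 0.05, adjusted p = 3.91e-12). With an estimated correlation this list had adjusted p = 0.193. Extracellular matrix and fibroblast genes rose too (adjusted p = 4.06e-07, median 0.50), with 26 of 43 members higher, 8 lower and 9 not called (29 and 8 adjusted over the list alone). TIMP3, an inhibitor of matrix proteases, rose by 2.84 (SE 0.10), the elastic fibre protein FBLN5 by 4.44 (SE 0.20) and the proteoglycan LUM by 2.15 (SE 0.11). This list had adjusted p = 0.238 with an estimated correlation.

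Replication-dependent histones were higher in CSB WT (adjusted p = 0.000106, median 0.68), with 15 of 24 members rising, 1 falling and 8 not called (17 and 1 adjusted over the list alone). H2AC6 rose by 0.93 (SE 0.06), H1-2 by 0.94 (SE 0.06) and H4C8 by 1.47 (SE 0.12). Most such messages lack a poly(A) tail and have near-identical copies, so their counts on poly-T capture are uncertain; adjusted p = 0.301 with an estimated correlation. Cholesterol synthesis genes rose (adjusted p = 0.0213, median 0.21), 13 of 25 higher, 2 lower and 10 not called, the same numbers adjusted over the list alone. HMGCS1 and SQLE, enzymes of the early and middle pathway, rose by 1.16 (SE 0.12) and 0.80 (SE 0.06), and the list had adjusted p = 0.931 with an estimated correlation. Neuronal genes rose (adjusted p = 0.0239, median 0.32), 10 of 19 higher, 3 lower and 6 not called, also the same adjusted over the list alone. SCG2, a secretory granule protein, rose by 3.94 (SE 0.20), the guidance receptor EPHA4 by 1.46 (SE 0.07) and the adhesion protein NLGN1 by 3.44 (SE 0.26). This call had adjusted p = 0.193 with an estimated correlation and ended without GFP control replicate 4 (adjusted p = 0.0704).

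Ribosome biogenesis and nucleolar factors were the 1 list that fell in CSB WT (adjusted p = 0.000874, median -0.19). Of the 92 tested members, 47 fell, 6 rose and 39 did not pass the test, and 51 fell and 7 rose adjusted over the list alone. EXOSC9 and DIS3, parts of the RNA exosome, fell (-0.74, SE 0.05, and -0.58, SE 0.06), as did UTP4, a factor of small ribosomal subunit assembly (-0.59, SE 0.06). DIS3 lies on autosome 13, whose tested genes had a median of -0.23 in this comparison. With an estimated correlation the list had adjusted p = 0.931. Nucleolin itself showed no detectable difference: NCL was at 1389 ± 131 CPM in CSB WT and 1460 ± 77.6 CPM in GFP control (-0.07, SE 0.07, adjusted p = 0.432). NPM1, a second abundant nucleolar protein, differed by 0.01 (SE 0.08, adjusted p = 0.897).

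Among genes of RNA polymerase I transcription, POLR1A and POLR1B, its largest subunits, fell in CSB WT (-0.25, SE 0.05, adjusted p = 0.001, and -0.34, SE 0.07, adjusted p = 0.000535). Smaller changes were the fall of the initiation factor RRN3 (-0.18, SE 0.06, adjusted p = 0.0158) and of the methyltransferase FBL (-0.23, SE 0.07, adjusted p = 0.0168) and the rise of the upstream binding factor UBTF (0.13, SE 0.04, adjusted p = 0.0189). The list of polymerase I genes as a whole did not pass (adjusted p = 0.432, 3 of 28 higher and 10 lower, likewise adjusted over the list alone). ATF3, a stress-induced repressor, fell by 0.61 (SE 0.10, adjusted p = 0.00012), and CDKN1A, a p53 target that stops the cell cycle, fell by 0.49 (SE 0.14, adjusted p = 0.0104). MDM2 (0.06, adjusted p = 0.438) and ERCC8, which encodes CSA (0.01, adjusted p = 0.919), gave no detectable difference. The calls of FBL, RRN3 and UBTF ended without single libraries. FBL reached adjusted p = 0.0651 without CSB WT replicate 1, 0.118 without CSB WT replicate 2, 0.0662 without GFP control replicate 1 and 0.0614 without GFP control replicate 3. RRN3 reached 0.105 without CSB WT replicate 1, 0.0553 without CSB WT replicate 4 and 0.0628 without GFP control replicate 2, and UBTF 0.0595 without GFP control replicate 4 and 0.0575 with no filter on low counts.

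None of the 6 list calls held with an estimated correlation (camera, 0 of 27 lists, against 4 at an unadjusted p under 0.05), while fry called 15 lists. The lists not called, among them p53 targets (adjusted p = 0.56) and cytosolic ribosomal proteins (0.908), lay between 0.0695 and 0.965.

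The UBD mutant against wild-type CSB is the comparison the design text names. Glycolysis and hypoxia targets and genes of the G2 and M phases were lower in UBD mutant, and no list was called higher. Neither list was called with an estimated correlation (adjusted p = 0.445 and 0.976 with an estimated correlation). In all, 6567 genes changed (43.7%), 3259 higher and 3308 lower in the mutant, and 1212 moved at least 2-fold, 510 higher and 702 lower. MT1E, the metallothionein with near-identical relatives, rose from 0.2795 ± 0.287 to 58.4 ± 15.6 CPM (7.65, SE 0.33, adjusted p = 5.87e-12). COL6A6 fell from 14.7 ± 0.509 to 0.0404 ± 0.00332 CPM (-8.34, SE 0.23, adjusted p = 2.24e-14).

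Further rises in the mutant were those of UCHL1, a ubiquitin hydrolase abundant in neurons (5.73, SE 0.13), ANKRD2 (4.92, SE 0.13), the stromal glycoprotein CD248 (4.22, SE 0.21) and CCDC102B (3.65, SE 0.14). TENM2, a teneurin, rose by 3.37 (SE 0.11) and NPR2, a natriuretic peptide receptor, by 3.14 (SE 0.16). PAGE5 rose by 3.60 (SE 0.16), uncertain because of near-identical family members. ATP10A, a lipid flippase, fell from 12.4 ± 1.75 CPM in CSB WT to 2 counts over the mutant libraries, a ratio of 616 with a 95% counting interval of 170 to 5100. CLEC2B (-8.57, SE 0.28), UGT2B7 (-7.39, SE 0.19), the metalloprotease ADAM33 (-7.01, SE 0.35) and CDH11, a mesenchymal cadherin (-6.92, SE 0.15), also fell. All had an adjusted p of 5.82e-11 or below in edgeR's test.

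Glycolysis and hypoxia targets fell in UBD mutant (camera adjusted p = 8.24e-07, median -0.27). Of these 37 members, 20 fell, 3 rose and 14 did not pass, the counts adjusted over the list alone being 20 and 3. GPI (-1.08, SE 0.04, adjusted p = 6.33e-13), ERO1A (-1.24, SE 0.05, adjusted p = 1.34e-12) and CA9 (-5.30, SE 0.30, adjusted p = 2.28e-10) fell. The list had adjusted p = 0.445 with an estimated correlation. G2 and M phase genes fell too (adjusted p = 0.000699, median -0.27), 35 of 47 lower, 6 higher and 6 not called, unchanged adjusted over the list alone. DLGAP5, TPX2 and ECT2, which serve the mitotic spindle and cytokinesis, fell (-0.78, -0.48 and -0.77, each with SE 0.05). For this list adjusted p = 0.976 with an estimated correlation. ERO1A and DLGAP5 lie on autosome 14, with a median of -0.04 here and windows of 25 neighbouring genes at -0.83 to 0.16. Which windows hold these genes was not examined. Of the S phase list, 6 of 41 members rose and 12 fell, likewise adjusted over the list alone, and it was not called (adjusted p = 0.884).

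Among the fixed nucleolar and polymerase I genes, POLR1B rose in UBD mutant against CSB WT by 0.23 (SE 0.07, adjusted p = 0.00984), and the others did not pass. NCL differed by -0.05 (SE 0.07, adjusted p = 0.6), NPM1 by -0.07 (SE 0.08, adjusted p = 0.467), FBL by -0.12 (SE 0.07, adjusted p = 0.215) and POLR1A by 0.07 (SE 0.05, adjusted p = 0.299). The ribosome biogenesis list was not called (adjusted p = 0.344), with 19 of 92 members higher and 8 lower, or 19 and 6 adjusted over the list alone, and it had adjusted p = 0.976 with an estimated correlation. Its members EXOSC9, from 39.5 ± 2.32 to 99.4 ± 2.92 CPM (1.33, SE 0.05, adjusted p = 2.15e-12), and DIS3 (0.52, SE 0.06, adjusted p = 7.2e-07) rose, and were chosen for this comparison after their values were seen. EXOSC9 lies on autosome 4, whose tested genes had a median of 0.23 here. DIS3 lies on autosome 13, with a median of 0.02 here and windows of 25 neighbouring genes at -0.10 to 0.38. Which window holds DIS3 was not examined. CDKN1A rose by 0.53 (SE 0.14, adjusted p = 0.00533) and ATF3 by 0.30 (SE 0.10, adjusted p = 0.025). The ATF3 call ended without CSB WT replicate 1 (adjusted p = 0.0703) or 3 (0.0509) and without UBD mutant replicate 1 (0.0628) or 2 (0.0849). UBTF (-0.06, adjusted p = 0.282), RRN3 (0.10, adjusted p = 0.158), MDM2 (-0.03, adjusted p = 0.71) and ERCC8 (0.17, adjusted p = 0.156) did not pass.

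Neither list call held with an estimated correlation (camera, 0 of 27 lists, against 2 at an unadjusted p under 0.05), and fry called 7 lists. The lists not called lay between adjusted p = 0.103 and 0.909, and without CSB WT replicate 3 the number called was 4 in place of 2.

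The UBD mutant against the GFP control showed higher extracellular matrix, histone and cholesterol synthesis genes, 3 of the lists that were also higher in CSB WT than in GFP control. Each had adjusted p = 0.999 with an estimated correlation. Here 6886 genes changed (45.8%), 3325 higher and 3561 lower in the mutant, with 1434 past 2-fold, 853 higher and 581 lower. ERCC6 was higher by 5.59 (SE 0.18, adjusted p = 9.71e-14). CACNG4, a calcium channel subunit, rose from 0.0569 ± 0.0264 to 13.1 ± 1.23 CPM (7.75, SE 0.25, adjusted p = 1.32e-13), and FBLIM1 from 0.153 ± 0.0707 to 32.3 ± 2.27 CPM (7.64, SE 0.17, adjusted p = 1.09e-15). PLAU, the urokinase protease, rose by 6.28 (SE 0.31), GALNT16 by 5.59 (SE 0.12), the growth factor gene PDGFB by 5.43 (SE 0.23) and UCHL1 by 5.24 (SE 0.13). PDE3A fell from 64.6 ± 6.07 to 0.0390 ± 0.0526 CPM (-10.47, SE 0.20, adjusted p = 2.24e-16), as did BRINP3 (-9.43, SE 0.26), ADAM33 (-6.34, SE 0.37) and FSTL5 (-6.13, SE 0.11). ATP10A fell to 2 counts, a ratio of 1490 with a 95% counting interval of 411 to 12300.

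Matrix and fibroblast genes rose in the mutant over GFP control (camera adjusted p = 1.31e-05, median 0.58), 24 of 43 higher, 7 lower and 12 not called (25 and 7 adjusted over the list alone). COL3A1, the chain of collagen III, went from 70.1 ± 23.5 to 941 ± 261 CPM (3.75, SE 0.26, adjusted p = 2.7e-09), POSTN, the matrix protein periostin, rose by 3.37 (SE 0.22) and TIMP3 by 3.18 (SE 0.10). Histones rose (adjusted p = 0.00373, median 0.56), 13 of 24 higher, 1 lower and 10 not called, the same adjusted over the list alone. H2BC5 rose by 0.91 (SE 0.05), H2AC6 by 0.84 (SE 0.06) and H1-2 by 0.81 (SE 0.06), with the same uncertainty from poly-T capture and copies. Cholesterol synthesis genes rose (adjusted p = 0.00517, median 0.27), 14 of 25 higher, 2 lower and 9 not called (16 and 2 adjusted over the list alone). HMGCS1 rose by 1.37 (SE 0.12) and MSMO1, an enzyme of the late pathway, by 0.86 (SE 0.08). For each of these lists, adjusted p = 0.999 with an estimated correlation.

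FBL fell in UBD mutant against GFP control by 0.34 (SE 0.07, adjusted p = 0.000865), and POLR1A fell by 0.18 (SE 0.05, adjusted p = 0.0112), a call that ended after a correction for GC content and length added after seeing the data (adjusted p = 0.114). NCL (-0.12, SE 0.07, adjusted p = 0.169), NPM1 (-0.06, SE 0.08, adjusted p = 0.559), POLR1B (-0.11, SE 0.07, adjusted p = 0.203), RRN3 (-0.08, SE 0.06, adjusted p = 0.279) and UBTF (0.07, SE 0.04, adjusted p = 0.183) did not pass. UBTF passed with that GC and length correction (adjusted p = 0.0441). ATF3 fell by 0.31 (SE 0.10, adjusted p = 0.0202), a call that ended without GFP control replicate 3 (0.0539) or 4 (0.0689) or UBD mutant replicate 4 (0.068). CDKN1A (0.05, adjusted p = 0.8), MDM2 (0.03, adjusted p = 0.712) and ERCC8 (0.19, adjusted p = 0.121) did not pass. Ribosome biogenesis factors were not called as a list (adjusted p = 0.147), though 37 of 92 fell and 5 rose, the same adjusted over the list alone. The mutant's 3 list calls were 0 of 27 with an estimated correlation (1 at an unadjusted p under 0.05) and 13 by fry, and the uncalled lists lay between 0.147 and 0.996.

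**Figure D3:**
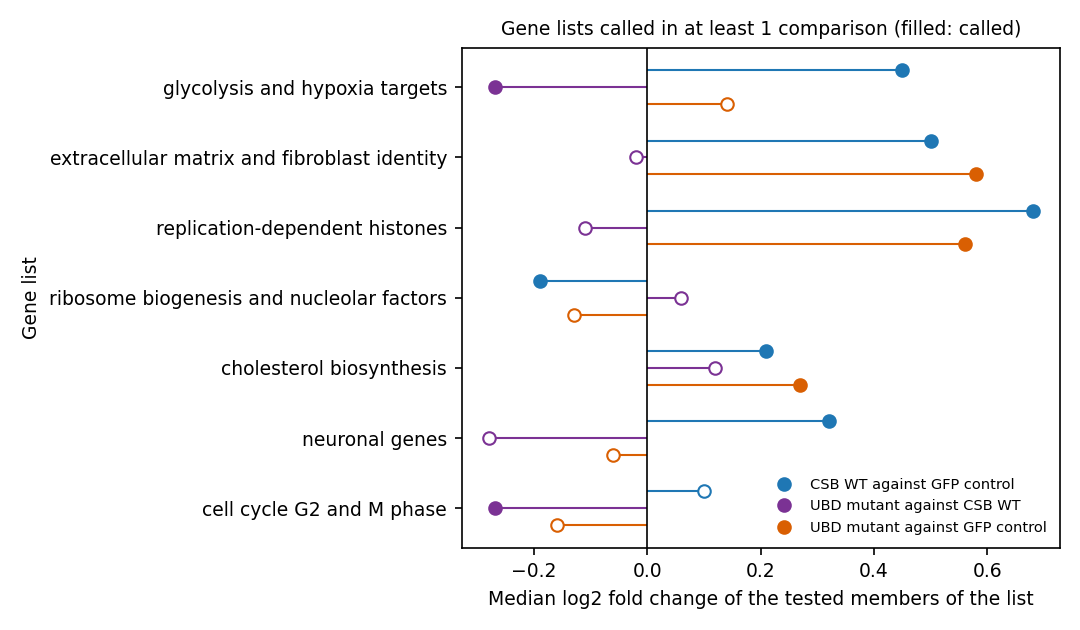
Median log2 fold change of the tested members of each list called in at least 1 comparison; colours are the comparisons, filled points passed the list test and open points did not. Glycolysis and hypoxia targets stood at 0.45 in CSB WT against GFP control, -0.27 in UBD mutant against CSB WT and 0.14 in UBD mutant against GFP control.

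Both CSB lines were set against the same GFP control libraries. In the same direction, 3475 genes changed in both, 1755 higher and 1720 lower, and 632 changed in opposite directions. Independent lists of these sizes share 1528 genes, and unchanged groups simulated against the same controls shared 0 (20 draws). That simulation held no changed gene, so its low overlap was set in advance. The log2 fold changes correlated across genes with r = 0.50, against 0.51 in the simulation, and their covariance was 0.375 against 0.024. With the 4 control libraries split so that each comparison had its own pair, 2438 to 2622 genes were shared (1021 for independent lists) and r was 0.44 to 0.47. Both pairs come from the same GFP control line, so the split removes only the noise of shared libraries. Differences particular to that line also give shared calls. A common effect of both CSB transgenes cannot be told apart from them. Genes are not independent replicates.

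Of the genes that changed in CSB WT against GFP control, 3077 moved back in UBD mutant against CSB WT and 758 moved further. Both comparisons use the CSB WT libraries, so opposite signs arise without any effect. Independent lists share 1456 genes, the simulation gave 0 on average and at most 1, and the covariance was -0.274 against -0.02 simulated. The correlation was -0.39 against -0.5 simulated. Splitting the CSB WT libraries left 2135 to 2268 genes, against 960 for independent lists. Both parts come from the same line, so the split removes only the noise of shared libraries. The simulation held no changed gene, so its low counts were set in advance. Differences particular to the CSB WT line also give opposite signs. A reversal by the mutant cannot be told apart from them.

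Genes of autosome 14 were higher in both CSB lines than in GFP control, and this chromosome holds GALNT16, BMP4, FBLN5, ERO1A and DLGAP5. Of its 493 tested genes, 328 rose and 23 fell in CSB WT against GFP control (median 0.45), and 290 rose and 49 fell in UBD mutant against GFP control (median 0.35). Against CSB WT, 98 rose and 164 fell in UBD mutant (median -0.04). The library medians differed in an exact 2-sided permutation test for each pair of lines (p = 0.0286, the smallest that 4 libraries against 4 can give, adjusted p = 0.0449 over 66 tests), and all 4 libraries of each CSB line lay above all 4 of GFP control. This test does not set autosome 14 apart, since 42 of the 66 tests had an adjusted p under 0.05, some with differences as small as 0.01. The median passed 0.2 in size in some comparison for 5 autosomes, which are given here by that rule, chosen after seeing the data. Besides autosome 14, autosome 21 had medians of 0.24 in CSB WT and 0.35 in UBD mutant against GFP control, and autosome 18 of 0.23 and 0.14. Autosome 13 stood at -0.23 and -0.12 in these comparisons, and autosome 4 at -0.10 and 0.12, with 0.23 in UBD mutant against CSB WT. Below that size, autosomes 9, 15 and 16 stood at -0.17, -0.14 and -0.11 in CSB WT against GFP control, autosome 15 at 0.13 in UBD mutant against CSB WT and autosome 16 at -0.11 in UBD mutant against GFP control. Windows of 25 neighbouring genes went further, to -1.33 on autosome 4 and 1.23 on autosome 21 in CSB WT against GFP control. On autosome 13, windows 6 to 9 stood at -0.54 to -0.44 in that comparison and windows 1 to 5 at -0.16 to 0.11. On autosome 18 in UBD mutant against GFP control, windows 1 to 3 stood at 0.82 to 0.98. Windows 4 to 8 there stood at -0.16 to 0.04. In UBD mutant against CSB WT, autosome 18 went from 0.77 in window 1 to -0.80 in window 8, around a median of 0.01.

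**Figure D4:**
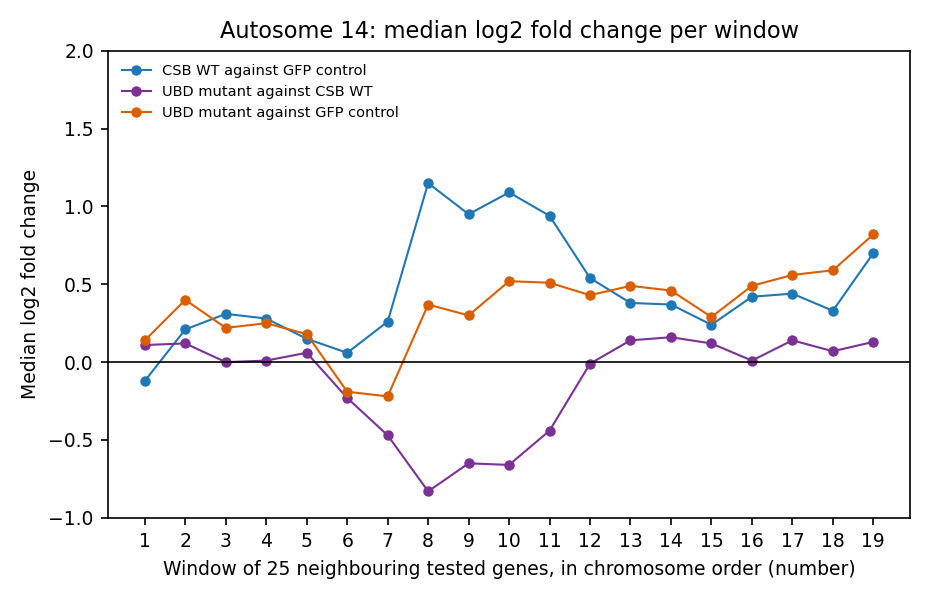
Median log2 fold change in 19 windows of 25 neighbouring tested genes along autosome 14, in chromosome order, with a line for each comparison. CSB WT against GFP control reached 1.15 in window 8 and 0.94 in window 11, where UBD mutant against CSB WT stood at -0.83 and -0.44.

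Markers of other cell types were low, and some moved with the lines. Epithelial, endothelial and leukocyte lists had 6, 7 and 7 tested members, too few for the list test. In CSB WT against GFP control, 4 leukocyte markers and 1 epithelial marker rose, and 2 endothelial markers rose and 3 fell. In UBD mutant against GFP control, 3 leukocyte markers rose and 1 fell, 3 epithelial markers rose, and 3 endothelial markers rose and 2 fell. In UBD mutant against CSB WT, 2 leukocyte markers rose and 1 fell, and 1 epithelial and 2 endothelial markers rose. The lists' other members did not pass. Their highest mean levels over the libraries were 17.4 CPM for KRT8, 3.07 CPM for ROBO4 and 11.01 CPM for CORO1A.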

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

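Of the tests in this part, those on the share of autosome 14 genes above 0 and on windows along that chromosome were set before their values were seen. The other splits of the samples, the corrections for GC content, length and position, the tests of harvest, ERCC6 level and depth and the count of genes on or off in 1 line were chosen only after the result was seen.

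CDKN1A, the p53 target that stops the cell cycle, stood at 12.03 CPM in CSB WT replicate 4 and at 7.615 to 7.934 CPM in the other CSB WT libraries, far apart for a group of 4. COL3A1, the chain of collagen III, was at 551.1 CPM in UBD mutant replicate 4 against 1044 to 1110 CPM in the others. NPM1, the nucleolar chaperone, was at 1361 CPM in that same library against 1144 to 1157 CPM. In GFP control, NPM1 was at 1210 CPM in replicate 3 against 1265 to 1272 CPM. SCG2, a secretory granule protein, was at 8.218 CPM in GFP control replicate 3 against 4.422 to 4.872 CPM, and TPX2, a spindle protein, at 433.3 CPM there against 462.6 to 468.1 CPM. The histone H1-2 was at 106.5 CPM in GFP control replicate 2 against 121 to 123 CPM, and NPR2 at 20.15 CPM there against 18.62 to 18.84 CPM. DLGAP5, another spindle protein, was at 97.15 CPM in GFP control replicate 4 against 101.4 to 102.1 CPM. In CSB WT, EPHA4 was at 53.88 CPM in replicate 1 against 48.5 to 49.25 CPM, LUM at 62.38 CPM in replicate 3 against 81.75 to 85.35 CPM, and CCDC102B at 2.031 CPM in replicate 4 against 1.579 to 1.603 CPM. FSTL5 was at 1.763 CPM in UBD mutant replicate 2 against 1.149 to 1.224 CPM. Genes of the mitochondrial chromosome took 1.48% of the counts in GFP control replicate 1 and 2.02% to 2.11% in the other GFP control libraries. These are 14 of 203 groups of 4 values examined, and chance alone sets apart about 1 group in 20.

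Genes of autosome 14 were higher in both CSB lines than in GFP control, with medians of 0.45 in CSB WT and 0.35 in UBD mutant. A few strong genes do not account for this, since they cannot move a median, and at least 78.7% of its 493 tested genes lay above 0 in either comparison. That share largely restates the medians and is no separate support. GC content or transcript length does not account for the pattern either, since the lower of both medians was 0.38 after that correction. More copies of the chromosome in both lines, or fewer in GFP control, may account for it. Of the windows of 25 neighbouring genes, 84.2% had a median over 0.1 in both comparisons. With medians of 0.45 and 0.35, scattered changes would also put most windows over 0.1, and both comparisons share the GFP control libraries. The window share thus cannot tell more copies from scattered changes. Windows 6 and 7 lay below 0 in UBD mutant against GFP control (-0.19 and -0.22), as did window 1 in CSB WT against GFP control (-0.12). These windows argue against an even change over the whole chromosome. Windows 8 to 11 stood out in CSB WT against GFP control (0.94 to 1.15), and were lower again in UBD mutant against CSB WT (-0.83 to -0.44). DNA was not measured, so this remains a hypothesis, and an effect of CSB on genes of this chromosome stays open.

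Glycolysis and hypoxia targets such as GPI, ERO1A and CA9 were higher in CSB WT than in both other lines, though the list calls were lost with an estimated correlation (adjusted p = 0.193 against GFP control and adjusted p = 0.445 for UBD mutant against CSB WT). Shifts of whole chromosomes are argued against by a list median of 0.29 on the lower side with each chromosome centred, and GC content or length by 0.27 after that correction. Centring does not remove shifts of single stretches. Both camera calls at the preset correlation held without the genes of the 5 shifted autosomes, a setting added after seeing the data. This argues against position on those autosomes, and stretches of other autosomes were not examined. All 4 CSB WT libraries lay above every other library in the list mean (0.31 to 0.42, against -0.30 to -0.17 in GFP control and -0.19 to -0.01 in UBD mutant). Oxygen or cell density at harvest and an effect of wild-type CSB both give this, and they cannot be told apart because each line is a group of its own.

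Large numbers of genes differed between the lines. In each comparison, 1 of 35 splits of the 8 libraries gave as many genes, the real one. It gave 6666, 6567 and 6886 genes for CSB WT against GFP control, UBD mutant against CSB WT and UBD mutant against GFP control. By edgeR, the highest other split gave 0, 0 and 2 (2413, 2224 and 2816 at an unadjusted p under 0.05). Every other split mixed 2 well-separated lines within a group, which widened the spread, so few calls were set in advance. With 1 line per group, the splits cannot exclude chance differences between lines. Depth is argued against because thinning to the smallest library left at least 96.5% of the calls. A response that grows with the ERCC6 level cannot be told apart from an effect of the variant, because both change between CSB WT and UBD mutant; 19.8% of the genes called in both steps moved further in the same direction, averaged over split CSB WT libraries. Drift between lines, unrelated to the transgene, cannot be told apart from a CSB effect: 43 protein-coding genes were on in 1 line only or off in 1 line only, at least 9 for each line, as when COL6A6 was on in CSB WT alone and BRINP3 in GFP control alone.

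The numbers of lists called by camera do not stand out among the splits. As many lists as the real 6, 2 and 3 came from 32, 34 and 33 of the 35 splits in the same order of comparisons, with up to 12, 13 and 13 lists in another split. Every other split mixed libraries of both lines within a group, and some kept part of the difference between the lines. Such splits do not show what chance alone gives, so they cannot decide whether chance accounts for these numbers. What raises the number of lists in other splits was not tested.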

How the results depend on the processing

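Leaving genes of 5 autosomes out of the list tests, the GC and length correction, thinning, all settings of the autosome medians and leaving libraries out of the ERCC6 level were chosen only after the result was seen; the other settings were planned. No call turned its direction, but medians near 0 of autosomes 13 and 18 changed sign. The numbers of changed genes were 6493, 6510 and 6783 by DESeq2 for CSB WT against GFP control, UBD mutant against CSB WT and UBD mutant against GFP control, and 6236 to 7042 over the other scalings, filters and models. At an absolute log2 fold change of at least 1 they were 1298, 1212 and 1434, with 627 shared against GFP control and 459 going back, since fewer genes pass. Leaving out 1 library gave 5826 to 6387, 5886 to 6402 and 6156 to 6740 genes, 3079 to 3486 shared and 2612 to 3009 going back. ERCC6 stayed at 33.3 to 39.6 CPM in CSB WT, 4.09 to 4.59 in GFP control and 200 to 226.5 in UBD mutant. Without GFP control replicate 1, the library with the low mitochondrial share, 6387 genes differed in CSB WT.

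List calls depended most on the test. With an estimated correlation camera called 0, 0 and 0 lists (4, 2 and 1 at an unadjusted p under 0.05), and fry called 15, 7 and 13. Without genes of the shifted autosomes, 7, 3 and 5 lists were called; for the last the cause was not tested. Leaving out 1 library gave 5 to 8, 2 to 4 and 3 to 4 lists. The 4 lists of UBD mutant against CSB WT came without CSB WT replicate 3, and the cause was not tested. For named genes, 1707 results kept their side of the threshold, 17 lost the threshold and 1 gained it, with sign changes of uncalled results counted as kept. For named lists, 131 kept and 12 lost it, all with an estimated correlation except the neuronal list without GFP control replicate 4 (adjusted p = 0.0704).

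After the GC and length correction, known for 97.1% of tested genes, autosomes 4, 13 and 21 stood at -0.08, -0.21 and 0.25 in CSB WT against GFP control, autosome 13 at -0.01 in UBD mutant against CSB WT and autosome 14 at 0.38 in UBD mutant against GFP control. With RLE size factors autosome 13 stood at -0.21 in CSB WT against GFP control. Leaving out 1 library gave for CSB WT against GFP control -0.11 to -0.07 on autosome 4, -0.23 to -0.19 on 13, 0.44 to 0.48 on 14, 0.20 to 0.27 on 18 and 0.25 to 0.28 on 21. For UBD mutant against CSB WT it gave 0.21 to 0.24 on autosome 4, 0 to 0.05 on 13, -0.06 to -0.02 on 14, -0.01 to 0.02 on 18 and 0.07 to 0.10 on 21. For UBD mutant against GFP control it gave 0.10 to 0.13 on autosome 4, -0.13 to -0.09 on 13, 0.35 to 0.39 on 14, 0.12 to 0.16 on 18 and 0.30 to 0.37 on 21. The cause was not tested for these shifts.

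The labels do not say that replicate numbers pair the libraries. Deviations of same-numbered libraries correlated at 0.142, 0.047, 0.145 and 0.151 between GFP control and UBD mutant, where each GFP control library correlated best with its own number, a hint from the data and not the design. With CSB WT included the correlations ran from -0.146 to 0.151, and 3 of 12 libraries correlated best with their own number in both other groups. With a replicate block, 6752, 6646 and 6938 genes, 6, 2 and 3 lists and overlaps of 3515 and 3159 genes were called. Settings planned for normalized values, a pseudocount and a filter on low values, were not run because counts were deposited. In simulated counts for CSB WT against GFP control, 56.7% of changes of 0.5 on the log2 scale were recovered, so smaller ones could be missed. Few genes were changed in that simulation, while 43.7% to 45.8% were called in the real comparisons, which loosens the adjusted cut-off. The simulated recovery thus does not give the sensitivity of the real comparisons.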

Other observations

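No test of cause was run on the families below, which were chosen after their values were seen, and in this part all tests were chosen only after the result was seen. Collagen genes, which build the fibres and basement membranes of connective tissue, were mostly higher in both CSB lines than in GFP control. Of 28 tested, 20 rose and 3 fell in CSB WT (median 0.73), and 17 rose and 3 fell in UBD mutant (median 0.66), with the same numbers under RLE scaling. In UBD mutant against CSB WT 8 rose and 11 fell (median -0.25). Some collagens, COL1A1 and COL6A3 among them, belong to the extracellular matrix and fibroblast list, so this is partly the same result. COL1A1, the main chain of collagen I, was at 4742 ± 222 CPM in GFP control, 6540 ± 774 CPM in CSB WT and 9186 ± 572 CPM in UBD mutant (SD, n = 4), and rose against GFP control by 0.46 and 0.95. Against the family median, COL1A1 was also higher in UBD mutant than in CSB WT (0.49). COL6A3, of collagen VI, rose by 1.24 and 0.98. COL7A1, the anchoring fibril collagen, went the other way, from 116.6 ± 31.0 CPM in GFP control to 19.34 ± 4.73 CPM in CSB WT and 29.3 ± 3.08 CPM in UBD mutant (-2.60 and -2.00). Protocadherin beta genes, a cluster of neuronal adhesion proteins with near-identical copies and so uncertain counts, rose in 10 of 12 cases and fell in 1 in CSB WT (median 0.81), with PCDHB5 higher by 1.80. In UBD mutant against CSB WT 6 of them fell and the others did not pass, and PCDHB5 fell by 0.58. In UBD mutant against GFP control 6 rose and the others did not pass (median 0.29), with PCDHB5 higher by 1.22.

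Genes of the UTP group, which assemble the small ribosomal subunit in the nucleolus, were lower in CSB WT than in GFP control in 9 of 11 cases and higher in UBD mutant than in CSB WT in 7 of 11 (medians -0.28 and 0.23). In UBD mutant against GFP control 2 were higher and 5 lower (median -0.13). UTP15 went from 22.75 ± 0.999 CPM in GFP control to 17.03 ± 1.08 CPM in CSB WT and 20.77 ± 0.919 CPM in UBD mutant. DDX helicases, grouped by symbol and most of which remodel RNA, showed 20 falls and 3 rises of 32 in CSB WT against GFP control (17 and 3 under RLE). They showed 4 falls and 11 rises in UBD mutant against CSB WT, and 13 falls and 5 rises in UBD mutant against GFP control (11 and 5 under RLE). DDX21, a nucleolar helicase, fell by 0.34 in CSB WT, and DDX5 fell by 0.23 there and rose by 0.20 in UBD mutant against CSB WT. Several of these genes are also in the ribosome biogenesis list.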
